A study of Arabidopsis thaliana with 17 samples.

How the data were processed

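CUT&RUN, in which an antibody-tethered nuclease releases the chromatin it is bound to, was done on sorted Arabidopsis thaliana nuclei with antibodies against histone H3 or H3K27me3, the mark set by Polycomb repressive complex 2, and with IgG or no antibody as controls. Endosperm nuclei of 6N content came from seeds of Col mothers pollinated by Ler, 4 days after pollination, and were profiled without fixation or after formaldehyde fixation, with 2 H3 and 2 H3K27me3 libraries for each treatment. Leaf nuclei of 3-week-old Col plants gave 1 library per antibody. Of the 17 samples, 5 H3K27me3 libraries have a domain list here (4 endosperm, 1 leaf). The H3 and H3K27me3 libraries of endosperm are also read through 1 table of parental counts. The IgG libraries and the tests on seed coat and embryo nuclei were not analysed here.

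Trim Galore, Bowtie2, Picard, deepTools 2.0 and SICER, and the genome build TAIR10, are named per the submitters' processing notes, without the step each was used for. The authors deposited 1 list of broad H3K27me3 domains for each library, and each list gives a p-value or q-value per domain (which of these is not given in the sources used here; all lie at or under 0.05) and an enrichment. The enrichments are log2 values that the authors computed before deposit; the base was read from the values, and the labels list each file under an H3K27me3 library and the H3 library of the same number. They were used only within a list. The authors also deposited 1 table of whole-number read counts in 150 bp bins, with a Col and a Ler column for H3K27me3 and for H3. Which libraries the columns hold, how reads were assigned to a parent and whether a read can be counted in more than 1 bin are not given in the sources used here; the labels list the table under the endosperm H3 and H3K27me3 libraries. The columns carry no replicate, so every parental value is a single value for the endosperm libraries as a pool. Depth per library is not known from the files. The nuclear bins held 12189039 allele-assigned reads for H3K27me3 and 7638577 for H3, in 552117 of 794273 bins.

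Positions are those of the authors' files on TAIR10, counted from 1. Genes came from the TAIR10.1 annotation (27444 nuclear protein-coding genes), whose nuclear chromosomes were taken to share the coordinates of TAIR10. As a check, 28 of 32 floral and meristem regulators were marked in leaf at their annotated places, against 7 and 6 when the genes were moved by 50000 bp in either direction. No annotation coordinate is printed. A gene was called marked in a list when domains covered at least 50% of its body, and marked in endosperm when this held in all 4 endosperm lists. Domain lists were compared by the Jaccard index of covered 150 bp steps, set against 1000 circular shifts within chromosomes, and fixed and unfixed lists by a two-sided exact permutation test. The 12 gene lists were fixed before the data were examined. Of 165 entries, 164 were kept (155 distinct genes), and 6 of these have no symbol in the annotation and are printed by locus tag; 1 was dropped because the annotation gives the locus another name. Marking of the lists was compared with all other genes by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over 24 tests. These tests run across genes within these libraries.

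The models planned for the parental counts, which needed counts per library, could not be fitted to pooled columns. In their place, the parental ratio of a gene is the log2 of Col:Ler in H3K27me3 over Col:Ler in H3, with 0.5 added to each count, for bins whose midpoint lies in the gene. H3 measured in the same bins carries the genome dosage of the endosperm (2 maternal, 1 paternal) and any mapping preference or reads from maternal tissue shared by both antibodies. It is therefore not a measure of dosage alone. Genes needed at least 40 allele-assigned reads per antibody and 10 Ler reads in H3. The error given is the counting SE multiplied by 1.74, the factor by which the 2 parts of a gene body differed beyond counting error in 6101 unmarked genes; this widening was chosen after the data were seen, as were centring on the median of genes marked in no list and random lists matched on H3K27me3 over H3. It covers counting error and local clumping of reads within these pooled libraries, and no variation between replicates. A gene or domain was called when its ratio was at least 2-fold and its 95% interval lay beyond 0. On simulated counts with the same extra spread, 59.0% of 200 genes changed by 1.5 on the log2 scale were recovered among 17986 genes, 73.0% of those changed by 2 and 86.0% of those changed by 3, with none in the wrong direction. Of unchanged genes, 3.59% to 3.72% were called. The simulations set unchanged genes at a ratio of 0, below the median of 0.91 of genes marked in no list, and used no centring. For a gene with no Ler read in H3K27me3 the ratio is given with 3 counts in place of 0, which leaves out the error of the other counts. H3K27me3 over H3 per gene was the log2 ratio of reads of both parents, scaled to the column totals, with the same error rule. List medians of the parental ratio were placed among 10000 random lists of equal size, matched on allele-assigned reads. The percentiles were not adjusted for the 12 lists. In simulations with 200 lists of 14 genes, all lists shifted by 1 on the log2 scale lay above the 97.5th percentile, and 1.00% of unshifted lists did. Shares of Col reads carry 95% Wilson intervals, which cover counting error only, and jackknife SEs over 1 Mb windows.

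Genes are named by a rule fixed in advance: the 8 largest called parental ratios per direction, every called member of the imprinted and type I MADS-box lists with up to 3 further members of each, list members marked in 1 tissue only (up to 10 per list) and otherwise the first 3 marked in both, up to 4 members per list with the largest called H3K27me3 over H3, and the 3 widest domains unique to a tissue. The rule's condition of an equal direction in every library pair was replaced by an equal direction in both parts of the gene body. Members of the lists that fall outside the rule are named in the text where they make up a count; they were chosen after their values were seen. Alternatives changed the cover that marks a gene, the enrichment and width of domains, the lists used, the read filter, the gene's limits, the centring of the parental ratio, the widening of the error and the bins used. Scripts used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.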

Results

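H3K27me3 was profiled by CUT&RUN in 6N endosperm nuclei of Col × Ler seeds, fixed or unfixed (2 H3K27me3 libraries each), and in Col leaf nuclei (1 library). The 5 domain lists held between 5878 (leaf) and 8403 (endosperm, unfixed replicate 2) nuclear domains. A table of parental read counts for endosperm held 11018316 Col and 1170723 Ler reads for H3K27me3, and 6201154 Col and 1437423 Ler reads for H3.

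The series set fixed against unfixed endosperm nuclei. Domains covered 19.8 and 20.1 Mb in the fixed libraries, 21.3 and 12.7 Mb in the unfixed libraries, and 20.5 Mb in leaf, which is 10.6% to 17.9% of the nuclear genome. In each list, 9.62% to 11.4% of the covered length lay in pericentromeric windows, which make up 26.2% of the nuclear genome, so the mark lay mostly on the chromosome arms in both tissues. The domain over FLC, a repressor of flowering, spanned 9900 bp (chromosome 5, 3172201 to 3182100) in fixed replicate 1, 13650 bp in fixed replicate 2 and 10500 bp in unfixed replicate 1. In unfixed replicate 2 it was split into domains of 1800 and 5400 bp. The domain over AP1, a floral identity gene, spanned 12300, 12750 and 12900 bp in the same 3 lists and was likewise split, into 3300 and 1650 bp, in unfixed replicate 2. Covered length averaged 19.9 ± 0.232 Mb in fixed and 17.0 ± 6.10 Mb in unfixed libraries (SD, n = 2 each). The difference of 2.96 Mb was smaller than the spread of the unfixed pair (exact permutation p = 1.00, two-sided; the smallest p this design allows is 0.333), and it turned to a fixed mean 1.36 Mb lower without unfixed replicate 2. That library also had the narrowest domains, with a median of 1200 bp against 1800 to 2250 bp in the other endosperm lists.

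**Figure D1:**
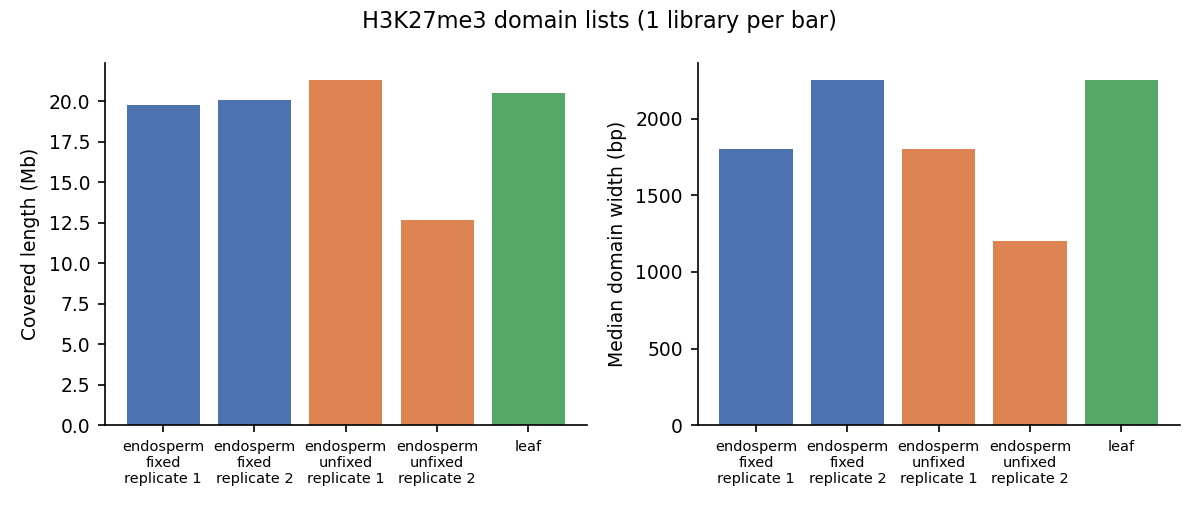
Length of the nuclear genome covered by H3K27me3 domains (left, Mb) and median domain width (right, bp) in each library, 1 bar per library, coloured by tissue and fixation. Unfixed replicate 2 covered 12.7 Mb, against 19.8 to 21.3 Mb in the other endosperm lists.

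Pairs of endosperm lists shared a Jaccard index of 0.521 ± 0.109 (SD over 6 pairs, which share libraries), and endosperm lists shared 0.449 ± 0.0819 with leaf (SD over 4 pairs). The fixed pair had the highest value, 0.640. Fixed and unfixed replicate 1 shared 0.606, and fixed replicate 2 and unfixed replicate 1 shared 0.613. Circular shifts never gave more than 0.158 in any pair (permutation p = 0.000999, the smallest that 1000 shifts can give). The 3 pairs with unfixed replicate 2 gave 0.418 to 0.427, below the 0.469 to 0.511 that the other 3 endosperm lists shared with leaf. Without that list, overlap was 0.620 ± 0.0179 within endosperm and 0.489 ± 0.0207 with leaf (SD, 3 pairs each). With 1 leaf library and an endosperm list further off than leaf, this gap cannot be assigned to the tissue.

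Endosperm was next compared with leaf, gene by gene. Some genes that act in the endosperm were marked in leaf and in no endosperm list: 3 of 10 endosperm regulators and 4 of 11 maternally expressed imprinted genes, while 4 of each were marked in no list. FIS2, a subunit of the seed Polycomb complex, was covered over 77.2% of its body in leaf and 7.16 ± 14.3% in endosperm (SD, n = 4, as for each endosperm cover below). FWA, an imprinted homeodomain gene, was covered over 54.8% in leaf and 0% in endosperm, and ZOU, a regulator of endosperm breakdown, over 69.5% and 0%. HDG8, another imprinted homeodomain gene, was covered over 100% in leaf (chromosome 3, 754951 to 759300) and 21.8 ± 4.20% in endosperm. MYB3R2 was at 65.3% in leaf and 0% in endosperm. In endosperm reads, H3K27me3 over H3 was log2 0.26 ± 0.18 for FIS2 and 0.25 ± 0.12 for HDG8 (widened SE). Both lay above the median of -0.54 for genes marked in no list, and part of HDG8 lay in a domain in each endosperm list. FIS2 and HDG8 thus did not lack the mark there. ZOU (-0.04 ± 0.22) and MYB3R2 (-0.16 ± 0.20) were nearer to that median, and FWA (-0.58 ± 0.27) was close to it. Of the 11 maternally expressed imprinted genes, 6 were marked in leaf and 1 in all endosperm lists, and of the 10 endosperm regulators and markers, 6 and 2. FIS2 and FWA belong to both lists, so these counts overlap. The exceptions marked in both tissues were MEA, MINI3 and ALE1.

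Of the floral regulators, 4 had no domain in any endosperm list. SEP1, SEP2 and SEP3, MADS-box genes of floral organ identity, were covered over 100% in leaf and 0% in every endosperm list, and SHP1, an ovule and fruit gene, over 92.7% and 0%. By reads, H3K27me3 over H3 in endosperm was log2 -0.50 ± 0.19 for SEP1, -0.17 ± 0.38 for SEP2 and -0.56 ± 0.21 for SEP3 (widened SE), but 0.73 ± 0.44 for SHP1, above the median of -0.54 for genes marked in no list. The leaf domain over SEP3 spanned 10500 bp (chromosome 1, 8590951 to 8601450) and was the second widest of 894 leaf domains that met no endosperm domain. The widest, of 14550 bp on chromosome 5 (24571201 to 24585750), covered HDA18 and its neighbours. The third, of 7950 bp on chromosome 2 (17189401 to 17197350), covered ORS1. Of the 21 floral and flowering-time regulators, 18 were marked in leaf and 7 in all endosperm lists, among them AP1, PI, FUL, FLC and FT. Among seed genes, OLEO2 and WOX8 were covered over 100% in leaf and in endosperm over 0% and, on average, 7.51%, with cover in 1 of the 4 lists. TT8, a regulator of seed coat pigment, was covered over 67.7% in leaf and 16.5 ± 18.1% in endosperm, and CUC3 over 55.6% and 21.6 ± 17.2%. The MADS-box gene AT3G05860 was at 89.5% in leaf and 0% in endosperm. By reads, TT8 (log2 0.78 ± 0.17) and WOX8 (0.45 ± 0.23) lay above the median of -0.54 in endosperm, so they did not lack the mark there. OLEO2 (0.17 ± 0.34) and AT3G05860 (0.06 ± 0.33) were nearer to it, and CUC3 had no allele-assigned reads.

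Among list members marked in all endosperm lists and not in leaf, SVP, a repressor of flowering active in leaves, was covered over 88.8 ± 22.4% in endosperm and 0% in leaf. The type I MADS-box gene AGL92 was covered over 100% in each endosperm list and 0% in leaf, and AGL23 over 98.2 ± 3.57% and 42.7%. RBCS3B, a Rubisco small subunit gene, was covered over 89.6 ± 13.0% in endosperm and 0% in leaf, although its near-identical neighbours can share reads with it; RBCS2B was marked in both tissues. PP2AA3, a common reference gene, was at 63.7 ± 14.7% in endosperm and 17.0% in leaf. The widest of 1118 stretches that lay in all endosperm lists and met no leaf domain were 10650 bp on chromosome 1 (3982951 to 3993600, over ADT1 and neighbours), 9150 bp on chromosome 5 (7867651 to 7876800, over MIA40 and neighbours) and 7200 bp on chromosome 1 (25457401 to 25464600, over AT1G67890 and AT1G67900).

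Over all genes, 2628 were marked in both tissues, 634 in all endosperm lists and not in leaf, and 807 in leaf and in no endosperm list. These classes ask for all 4 lists on one side and none on the other: 2884 genes were marked in any endosperm list and not in leaf, and 4776 in any and in leaf. At 80% cover the counts were 375 in all endosperm lists and not in leaf, 1515 in both and 884 in leaf alone. In fixed lists only, 1042 genes were not in leaf, and 1304 were in leaf alone against unfixed lists only. Leaf has 1 library, so the comparison has no test. Of genes marked in 3 endosperm lists, 3.78% to 5.23% were missing from the fourth and 19.4% to 20.8% from leaf when either fixed list or unfixed replicate 1 was the fourth. When unfixed replicate 2 was the fourth, 22.9% were missing from it and 21.5% from leaf, so that the loss in leaf exceeded the replicate error against 3 of the 4 lists.

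Some developmental classes were marked in both tissues. Of 18 embryo and seed maturation genes, 12 were marked in endosperm and 17 in leaf, among them the master regulators FUS3 and ABI3 and the storage protein gene CRA1. Of 11 meristem and boundary regulators, 7 were marked in endosperm (STM, KNAT2, KNAT6 and CUC2 among them) and 10 in leaf, and of 9 root regulators, 7 were marked in each, among them RHD6, RSL4 and PLT1. Marking in endosperm exceeded that of other genes (11.9%) for seed maturation genes (66.7%, adjusted p = 5.80e-07, Fisher's exact test with Benjamini-Hochberg adjustment, as for all list values here), root regulators (77.8%, adjusted p = 4.63e-05), paternally expressed imprinted genes (56.2%, adjusted p = 9.77e-05), meristem regulators (63.6%, adjusted p = 0.000244), type I MADS-box genes (40.0%, adjusted p = 0.00318) and floral regulators (33.3%, adjusted p = 0.0171). In leaf, where 20.3% of other genes were marked, the values (Fisher's exact tests) were 94.4% for seed maturation genes (adjusted p = 5.99e-10), 85.7% for floral regulators (adjusted p = 2.93e-09), 90.9% for meristem regulators (adjusted p = 6.49e-06), 62.5% for paternally expressed genes (adjusted p = 0.000857) and 77.8% for root regulators (adjusted p = 0.000934). Endosperm regulators (60.0%, adjusted p = 0.0152) and maternally expressed imprinted genes (54.5%, adjusted p = 0.0234) also exceeded the rest in leaf by the same exact test, and neither did in endosperm (20.0%, adjusted p = 0.450; 9.09%, adjusted p = 1.00). At 80% cover, leaf marking of endosperm regulators (30.0%, adjusted p = 0.368) and of maternally expressed genes (18.2%, adjusted p = 1.00) and endosperm marking of meristem regulators (27.3%, adjusted p = 0.0773) no longer passed the exact test. Leaf marking of maternally expressed genes was also lost with any overlap (adjusted p = 0.127) and among the upper 75% of domains (adjusted p = 0.173), and marking of type I MADS-box genes in any endosperm list, rather than all, did not pass (adjusted p = 0.217; exact tests). Whether the tissues differ for these lists was not tested. The lists share members: FIS2 and FWA are leaf-marked in both the endosperm regulators and the maternally expressed genes. PHE1 and AGL92 belong to both the paternally expressed and the type I MADS-box genes. The exact tests also take members as independent. Yet AGL86 and AGL92 lay in the same domain of 16500 bp in fixed replicate 2, and PHE1, PHE2 and AGL23 lay close together on chromosome 1. Seed coat markers (14.3% in endosperm, 42.9% in leaf), photosynthesis genes (13.3% and 6.67%), housekeeping genes (9.09% and 0%) and Polycomb repressive complex 2 genes (1 and 2 of 8) did not pass in either tissue, nor did type I MADS-box genes in leaf (35.0%). Without unfixed replicate 2, endosperm marking was 35.7% for seed coat markers (exact test, adjusted p = 0.0829) and 47.6% for floral regulators; in fixed lists only it was 35.7% and 52.4%, and in any endosperm list 42.9% and 81.0%.

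**Figure D2:**
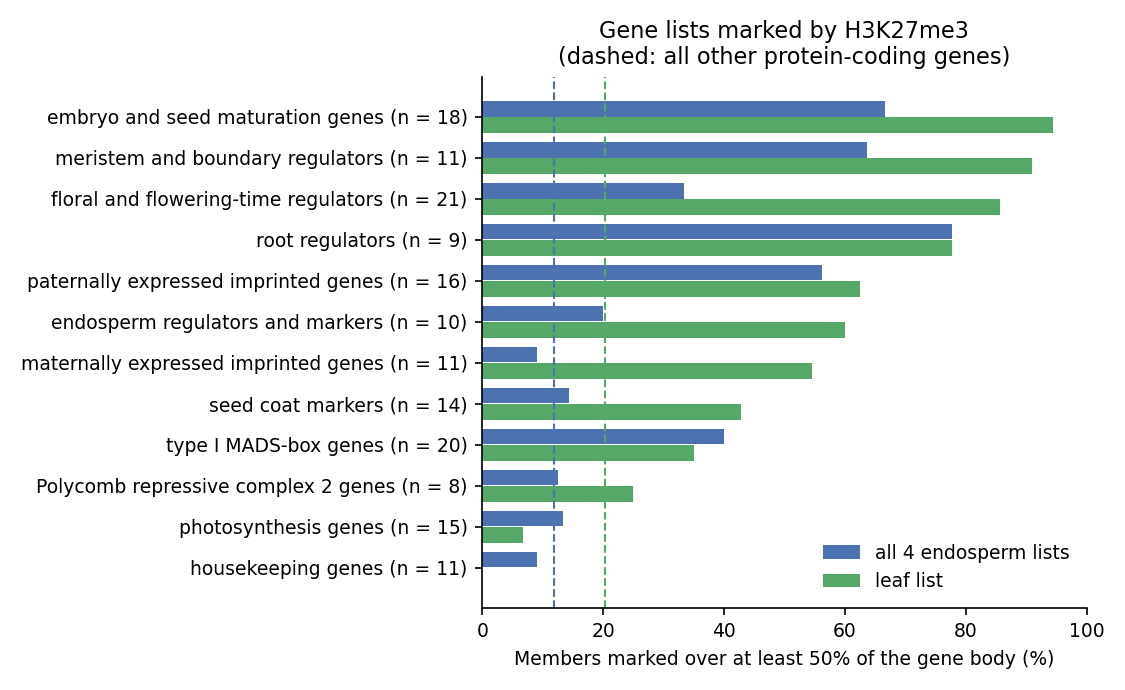
Percentage of each list's members (x axis) with H3K27me3 domains over at least 50% of the gene body in all 4 endosperm lists (blue, upper bar) and in the leaf list (green, lower bar); dashed lines give all other genes (11.9% and 20.3%). Floral regulators stood at 33.3% in all endosperm lists (81.0% in any) and 85.7% in leaf, and root regulators at 77.8% in both tissues.

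Read counts of both parents gave the level of H3K27me3 over H3 per gene in endosperm, scaled to the totals. Among developmental regulators, high values belonged to WOX9 (log2 2.64 ± 0.36, widened SE, as below), FUL (2.33 ± 0.25), CUC2 (2.24 ± 0.14) and FLC (2.19 ± 0.19). Among imprinted genes, AT1G49290 reached 2.37 ± 0.19, ADM 1.91 ± 0.25, VIM5 1.84 ± 0.11 and TAR1 1.84 ± 0.30. AGL23 stood at 1.99 ± 0.21, PHE1 at 1.62 ± 0.62 and AGL86 at 1.43 ± 0.20. The seed coat genes MYB5 (2.16 ± 0.48) and TT16 (1.57 ± 0.14) and the root regulators RSL4 (2.02 ± 0.57) and PLT1 (1.68 ± 0.22) were also above H3. At the other end stood AGL80 (0.379-fold), the housekeeping genes UBC9 (-1.29 ± 0.63), ACT7 (-1.11 ± 0.46) and UBQ10 (-1.09 ± 0.26), the photosynthesis gene GAPB (-1.13 ± 0.29) and the seed coat gene AHA10 (-1.09 ± 0.30). Of the same photosynthesis list, RBCS3B (1.91 ± 0.47) and RBCS2B (1.62 ± 0.43) were above H3. Of 22719 genes with enough reads, 2157 were at least 2-fold above H3 and 2469 at least 2-fold below. The genes above H3 took in 60.9% of genes marked in all endosperm lists (median 1.16) and 0.302% of genes marked in no endosperm list (median -0.51). Genes marked in no list had a median of -0.54 on this scale, and relative to it 4632 genes were above and 441 below; AGL80, UBC9, ACT7, UBQ10, GAPB and AHA10 were then less than 2-fold below.

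Reads were then split by parent, to ask whether the maternal (Col) and paternal (Ler) genomes carry the mark alike. Col reads made up 90.4% of H3K27me3 reads (95% Wilson interval 90.38% to 90.41%; jackknife SE 0.166) and 81.2% of H3 reads (81.15% to 81.21%; SE 0.0972), where a 2 to 1 genome dosage alone would give 66.7%. The difference was 9.21 percentage points, and on the 5 chromosomes the Col share lay between 89.7% and 91.0% for H3K27me3 and between 80.9% and 81.3% for H3. The Col share of H3 lay above 66.7%, as a mapping preference for Col or reads from maternal tissue would give, which was not tested. The difference between H3K27me3 and H3 was larger inside domains. Outside every endosperm domain Col made up 88.5% of H3K27me3 reads, and inside domains of all 4 lists 93.9%, while H3 stayed at 81.2% and 81.3%. From the first to the second kind of bin, H3K27me3 reads per H3 read rose from 1.24 to 4.64 on the Col genome (3.74-fold) and from 0.697 to 1.31 on the Ler genome (1.88-fold). In domains of all endosperm lists without a leaf domain, the ratio rose 3.39-fold on Col and 1.49-fold on Ler. Domains were called on libraries whose allele-assigned reads are mostly Col, so sorting bins by them favours high H3K27me3 on Col. Sorted by leaf domains, which come from other nuclei, though of Col plants, the ratio was 1.41 outside and 3.34 inside on Col, and 0.731 and 1.18 on Ler. With counts pooled over libraries, these differences have no replicate check.

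**Figure D3:**
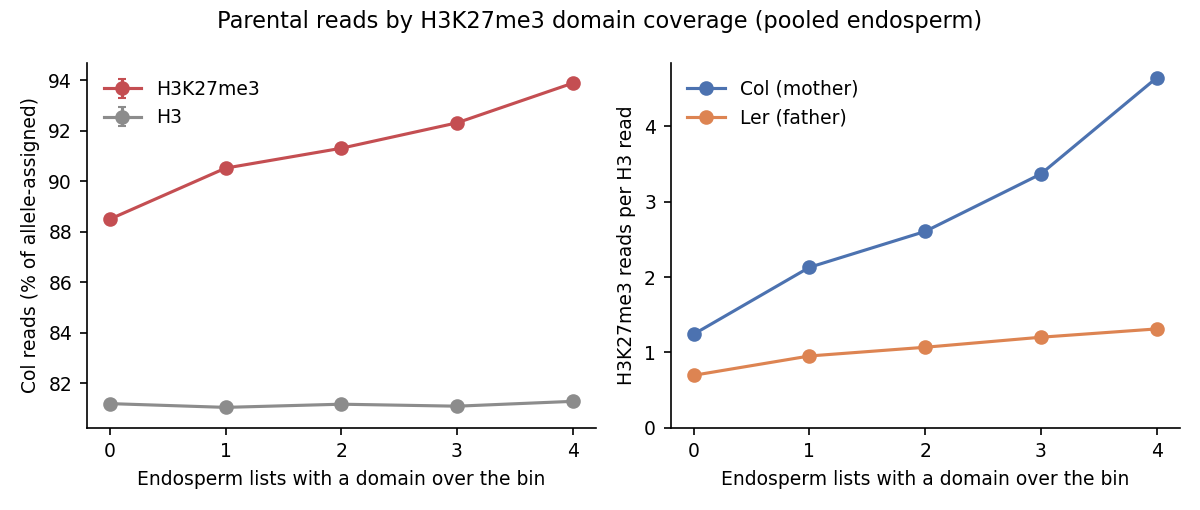
Col share of allele-assigned reads (left, %; error bars, jackknife SE, smaller than the points; the axis does not start at 0) and H3K27me3 reads per H3 read on each parental genome (right) for bins by the number of endosperm lists with a domain there. The Col share of H3K27me3 goes from 88.5% to 93.9% while that of H3 stays near 81.2%, and the ratio reaches 4.64 on Col and 1.31 on Ler.

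Per gene, the parental ratio leaned toward the mother. Genes marked in no list had a median log2 ratio of 0.91, and values below are relative to this median unless stated. Genes marked in all endosperm lists stood 0.94 above it (2137 genes), by 1.17 where leaf lacked the mark (463 genes) and by 0.86 where leaf had it (1674 genes), whereas genes marked in leaf and in no endosperm list stood 0.17 above it (499 genes). With no centring, 5935 of 17986 genes were called toward Col and 13 toward Ler. Relative to unmarked genes, 1206 were called toward Col and 424 toward Ler, and with the overall Col:Ler ratio of each antibody removed, 740 and 802. Calls toward Col thus made up 99.8%, 74.0% and 48.0% of all calls under the 3 scalings. Of the 12500 genes marked in no list, 232 were called toward Col and 383 toward Ler relative to their own median. Calls toward Ler relative to unmarked genes were 2.36% of tested genes. The simulations called 3.59% to 3.72% of unchanged genes, both directions together. They set unchanged genes at a ratio of 0 and used no centring, so this share cannot be carried over to centred calls. False calls can still make up much of the 424 and part of the 1206, and their number was not measured. Among genes marked in all endosperm lists, 679 were called toward Col and 11 toward Ler relative to unmarked genes. Marking in endosperm rests on libraries whose allele-assigned reads are mostly Col. Choosing genes by it favours high H3K27me3 on Col, here and in the medians of marked genes above.

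Paternally expressed imprinted genes, named for expression mainly from the paternal copy, had the highest list median, 1.62 above unmarked genes (14 tested, 100th percentile of matched random lists). Of the 14, 9 were called toward Col relative to unmarked genes and none toward Ler, and 11 with no centring. PKR2, a chromatin remodeller, stood at 3.00 ± 1.02 (378 Col and 9 Ler reads for H3K27me3, 62 and 23 for H3). The auxin synthesis gene YUC10 stood at 2.53 ± 0.61, ADM at 2.44 ± 0.72, VIM5, a methylcytosine-binding protein gene, at 2.39 ± 0.38 and the histone methyltransferase gene SUVH7 at 2.11 ± 0.45. AT1G49290 stood at 2.09 ± 0.57, HDG3 at 1.66 ± 0.56, ORTHL at 1.27 ± 0.45 and SUVH8 at 1.08 ± 0.54; SUVH8 lost its call with the overall ratio removed (0.86). VIM5, ORTHL and the SUVH pair have close relatives that can share reads. TAR1 (1.58 ± 1.02) and AGL92 (0.44 ± 0.53) were called with no centring only. NRPD1, with 0% cover in leaf and 7.17 ± 8.32% cover in endosperm, stood at 0.04 ± 0.29, and JMJ15 at -0.85 ± 0.52 and, with no centring, at 0.06; JMJ15 was called toward Ler (-1.07) only with the overall ratio removed. PHE1 had 90 Col and 5 Ler reads for H3K27me3 and 14 and 5 for H3, too few to be tested.

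Type I MADS-box genes had a median 0.88 above unmarked genes (10 tested; 98.2th percentile). AGL86 stood at 2.57 ± 0.74 and AGL23 at 2.16 ± 0.72. AGL34 (2.12 ± 1.14), AGL61 (0.76 ± 0.63) and PHE2 (0.75 ± 0.72) were called with no centring only, and AGL62, which restrains endosperm cellularisation, stood at -0.29 ± 0.65. Meristem regulators (98.8th percentile, 8 tested; median 2.01 with no centring) and floral regulators (0.69, 98.5th percentile, 20 tested) were also high, with KNAT2 at 2.44 ± 0.57, STM at 1.69 ± 0.39, FLC at 1.60 ± 0.57 and AP1 at 1.36 ± 0.51. FUS3, of the seed maturation list (0.46, 87.8th percentile, 12 tested), reached 3.50 ± 0.78. Against random lists matched on H3K27me3 over H3, the paternally expressed genes stayed high (99.6th percentile), and the MADS-box (89.8th), meristem (64.7th) and floral (55.3rd) lists lay within the random range. Percentiles are not adjusted for the 12 lists, and this matching was chosen after the data were seen.

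Maternally expressed imprinted genes stood at 0.39 (75.5th percentile, 10 tested). FWA stood at 1.80 ± 1.04, SDC at 0.57 ± 0.63, FH5 at 0.40 ± 0.41 and HDG8 at 0.38 ± 0.36, called with no centring only, while FIS2 was also called relative to unmarked genes, at 1.07 ± 0.50, and not with the overall ratio removed (0.85). AGL36 (1.52, on 4 Ler reads for H3K27me3), MPC (0.38 ± 0.98) and MYB3R2 (-1.17 ± 0.62) were not called with no centring, and MEA had no allele-assigned reads. Endosperm regulators stood at 0.34 (69.0th percentile), seed coat markers at 0.23 (46.0th), root regulators at 0.47 (78.0th), photosynthesis genes at -0.02 (29.9th), housekeeping genes at 0.07 (40.6th) and Polycomb repressive complex 2 genes at 0.06 (34.3th, 3 tested).

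**Figure D4:**
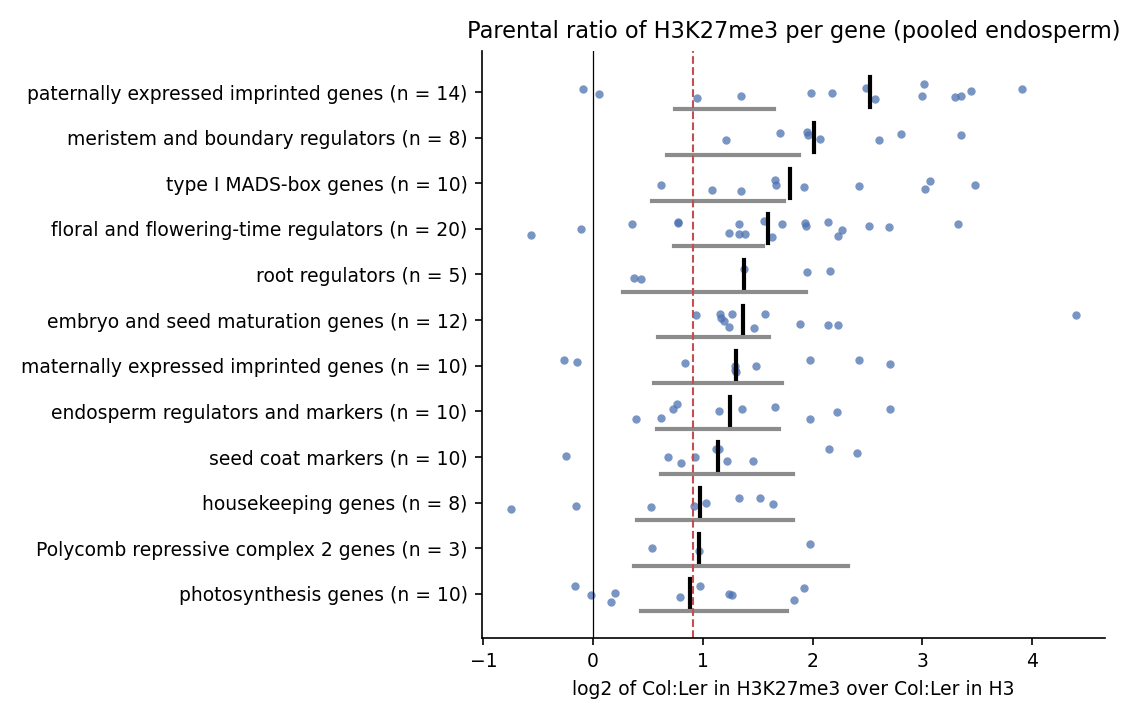
Log2 of Col:Ler in H3K27me3 over Col:Ler in H3 (x axis, no centring) for each tested list member (points), with list medians (black ticks), the central 95% of medians of matched random lists (grey bars), 0 (solid line) and the median of unmarked genes (dashed line, 0.91). The paternally expressed genes have a median of 2.53, outside their grey bar.

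The largest single ratios rested on few Ler reads for H3K27me3, and some also on a low Col share in H3. They are given here with no centring. MPK5, a kinase gene marked in every endosperm list and not in leaf, had 438 Col and no Ler reads for H3K27me3 and 66 and 17 for H3, a log2 ratio of 5.27 with 3 counts in place of 0. AT5G46820 had 428 and none, against 101 and 25, and 5.17 by the same rule. The ratios on which these genes were ranked and called, with 0.5 added to each count, were 7.85 ± 3.61 for MPK5 and 7.75 ± 3.59 for AT5G46820. These widened SEs let the true ratio lie far lower. RALFL11 stood at 5.26 ± 1.75, AT1G72920 at 5.73 ± 1.33 and AT5G40595 at 5.18 ± 2.20, all marked in every endosperm list. DOR (6.04 ± 2.14), PMEI2 (5.86 ± 2.22) and MEE47 (5.12 ± 2.19) were marked in no endosperm list, though DOR was covered over 100% in leaf. H3 held 42 Col and 35 Ler reads for DOR, 16 and 24 for PMEI2, 29 and 21 for MEE47 and 33 and 41 for AT1G72920. In all nuclear bins, H3 was 81.2% Col. Such a Ler excess in H3 raises the ratio whatever H3K27me3 does, so these ratios do not show loss of the mark on Ler alone. H3K27me3 over H3 was log2 -0.05 for DOR, -0.12 for PMEI2 and -0.15 for MEE47. MPK5, AT5G46820, AT5G40595 and MEE47 were called with no centring only: relative to unmarked genes AT5G40595 (4.27 ± 2.20) and MEE47 (4.21 ± 2.19) stayed high, and the calls ended through the wide errors at 0 or 1 Ler reads. With 500 bp added on each side, all 8 stayed called at lower ratios: PMEI2 5.60, MPK5 4.75, AT1G72920 4.25, RALFL11 3.67, DOR 3.66, AT5G46820 2.89, AT5G40595 2.20 and MEE47 1.50. Toward Ler, the 8 largest genes were all unmarked in both tissues: LCL1 (-2.15 ± 0.88), AT5G01150 (-1.90 ± 0.94), AT5G41870 (-1.87 ± 0.84), COP13 (-1.82 ± 0.87), RLP51 (-1.79 ± 0.73), AT5G01230 (-1.78 ± 0.78), AT5G09620 (-1.72 ± 0.85) and AT5G55550 (-1.66 ± 0.79). With 500 bp added on each side, 4 of these lost their call: AT5G01150 (-1.01), COP13 (-0.64), RLP51 (-0.55) and AT5G09620 (-1.31). All 8 had few Ler reads in H3, from 10 (LCL1) to 22 (AT5G09620), where the filter asked for 10. LCL1 had 168 Col and 10 Ler reads for H3, and 196 and 54 for H3K27me3. A low Ler count in H3 lowers the ratio whatever H3K27me3 does. H3K27me3 over H3 of the 8 lay between log2 -1.78 (AT5G09620) and -0.19 (LCL1).

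Among 6097 merged endosperm domains with enough reads, 3158 were called toward Col and 1 toward Ler with no centring, and 728 and 53 relative to unmarked genes. These domains were called on libraries whose allele-assigned reads are mostly Col, which favours calls toward Col. With no centring, the stretch over MIA40 and its neighbours on chromosome 5, found in all endosperm lists and not in leaf, had 7151 Col and 163 Ler reads for H3K27me3 against 1086 and 219 for H3 (3.14 ± 0.27). The one over AT1G67890 and AT1G67900 stood at 2.43 ± 0.73, and the one over ADT1 had no allele-assigned reads. The leaf-only stretch over SEP3 stood at 0.07 ± 0.34 in endosperm, that over HDA18 at 0.71 ± 0.36 and that over ORS1 at -0.11 ± 0.90.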

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

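Domains on the chloroplast genome, outside the nuclear domains the comparisons use, stood in the lists of fixed replicate 1 (7 domains, 8700 bp, median log2 enrichment 0.71) and fixed replicate 2 (26 domains, 67200 bp, 2.41). Both unfixed lists and the leaf list had none. Whether fixed and unfixed libraries differ in this was not tested, and no value of the 4 endosperm lists tested for a library far from the others (number, covered length, median width, pericentromeric share and median enrichment of domains, repeated enrichment values and genes marked) passed the limit of Dixon's test for 4 samples. Covered length of unfixed replicate 2 came closest, with a gap of 0.824 of the range.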

How the results depend on the processing

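Error widening, centring on unmarked genes, even and odd bins, the removal of bins lacking Ler reads, random lists matched on H3K27me3, list pairing, sorting by leaf domains and the lists left out for covered length and overlap were chosen after seeing the data. Covered length (fixed minus unfixed, 2.96 Mb) was the same with lists paired by replicate number as a block, 2.96 Mb (exact sign-flip p = 1.00; smallest possible 0.5), where the labels share only a number; leaving out each list gave -1.36 to 7.27 Mb, reversed without unfixed replicate 2. No paired analysis was possible because the parental table has no library columns, so for it the replicate block, leave-one-out, single fixations, fixation-dependent tests, the planned count-model fits and their alternatives were not run. Counting domains overlapped over 50% of their length gave 0.650 within endosperm and 0.583 with leaf, by its construction another measure. At 80% cover, 375 genes were marked in endosperm and not in leaf and 1515 in both; in any endosperm list, 2884 and 4776; in fixed lists only, 1042 were not in leaf; in unfixed lists only, 1304 were in leaf alone. Of 156 list tests under alternatives that can change the marking, 149 kept their side of the threshold (84 leaf tests, whose marking is fixed where only endosperm lists change, are left out); 6 losses are given beside the results, and leaf marking of seed coat markers passed among the upper 75% of domains (exact test, adjusted p = 0.0428).

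Parental calls toward Col and Ler were 23 toward Ler with no read filter, 740 and 802 with the overall ratio removed, 1206 and 424 relative to unmarked genes, 1541 and 0 in genes marked in all endosperm lists (679 toward Col relative to unmarked genes), 2737 and 0 in even bins, 2702 and 0 in odd bins (fewer reads per gene) and 9199 and 85 with the error not widened. For domains they were 2 toward Ler with no filter, 465 and 116 with the ratio removed, 728 and 53 relative to unmarked genes, 2074 and 0 in even bins, 2091 and 0 in odd bins, 0 toward Ler without bins lacking Ler reads and 5 toward Ler with the error not widened. Relative to unmarked genes, 4632 genes were above H3. Matched on H3K27me3, 1 list lay outside the random range, against 4. The Col difference was 11.3 points inside domains, 7.31 outside, 9.84 without pericentromeric bins, and 11.1 inside and 8.14 outside leaf domains. Where construction does not give the cause, the cause was not tested. Of 42 named genes, 13 lost their call relative to unmarked genes and 15 with the overall ratio removed, which gave JMJ15 a call toward Ler (-1.07). Among uncalled genes, NRPD1 (-0.18) and AGL62 (-0.51) turned sign with that ratio removed, and JMJ15 (-0.85) and AGL62 (-0.29) relative to unmarked genes. With 500 bp on each side 4 lost their call and AGL36 gained one (2.57).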

Other observations

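All tests below except that of domain containment were chosen after the result was seen.

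Members of the lists that were not marked in any list included the endosperm regulators IKU2, EDE1, ICE1 and AGL62, and the Polycomb genes CLF, SWN, FIE, EMF2 and MSI1. Of the 20 type I MADS-box genes, 10 were marked in no list. Genes with no Ler read in H3K27me3 numbered 105 of 17986, and 91 of them were marked in no endosperm list. In bins with at least 10 Ler reads in H3, 7.42% outside domains had no Ler read in H3K27me3, where a Poisson distribution with their mean of 4.36 would leave 1.28%; inside domains of all 4 lists it was 2.03%, against 0.0525% with a mean of 7.55. In the other direction, 60 genes had no Ler read in H3 and at least 10 in H3K27me3.

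H3K27me3 reads were more maternal than H3 reads even outside every endosperm domain. The log2 ratio there, 0.83 ± 0.0194 (jackknife SE), is that pattern itself, so it does not test a mapping preference, which stays open where it differs between the antibodies. Untargeted reads from maternal tissue in the H3K27me3 libraries stay open too: the 13 windows of 1 Mb with the least H3K27me3 had a median of 0.34 against 0.91 in the others, but most of the reads that rank the windows are Col, so low windows favour low ratios. H3K27me3 of seed coat nuclei, which the 6N sort should reduce, could still contribute, since seed coat markers lay at the 25.7th percentile of lists with like H3K27me3, inside the random range, and the seed coat's own domains were not analysed here. H3 itself was 81.2% Col outside every endosperm domain, above the 66.7% of dosage, as maternal nuclei or a mapping preference for Col would give. A maternal genome that carries more of the mark outside called domains stays open as well, as untested.

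Paternally expressed imprinted genes had a larger maternal excess than genes with like H3K27me3. Few Ler reads are unlikely to account for this alone. The list's median of 2.53 lay at the 99.7th percentile of random lists with like H3K27me3 and like Ler reads in H3 (95% range 1.31 to 2.30). That percentile is not adjusted for the 12 lists. Maternal tissue with the leaf's domains would add the mark to every leaf-marked gene, but the 9 leaf-marked maternally expressed and endosperm genes (MINI3 and ALE1 also marked in all endosperm lists) had a median log2 ratio of 1.29, below the bootstrap interval of the 9 leaf-marked paternally expressed genes (median 3.02, 2.48 to 3.44). The 2 sets were not matched on level: H3K27me3 over H3 was lower in the maternally expressed and endosperm genes (median log2 0.10 against 1.70). The parental ratio rose with level in these data, from 0.83 outside every endosperm domain to 1.82 inside all 4 lists. The comparison therefore cannot decide whether such tissue is the whole cause. Maternal tissue, with the leaf's domains or others, stays open. So does more of the mark on the maternal copies in endosperm, which was not tested apart from it.

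Unfixed replicate 2 covered the least of the genome. If lower depth were the cause, its domains were predicted to lie within those of the other 3 endosperm lists over at least 90% of their length and to repeat enrichment values most often. They lay within them over 87.5%, inside the range of 85.2% to 89.7% of the other lists, and 89.3% of its domains repeated an enrichment value, against 70.3% to 75.8% in the others. Lower depth is a possible explanation that these values do not decide, because the files give no depth per library. No biological explanation was tested, since the labels give this library the same group as unfixed replicate 1.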
